A study of Mus musculus with 18 samples.

How the data were processed

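RNA was measured in germ cells of the ICR mouse testis. Per the labels' protocols, 6 germ cell types were separated by STA-PUT velocity sedimentation, in which cells settle through a gradient at a speed set mainly by their size. Per the same protocols, total RNA was extracted with Trizol and made into libraries with the Illumina TruSeq RNA kit, and sequencing was done by Illumina instruments. The type labels are priSG-A (postnatal day 6), priSG-B (day 9), plpSC (day 14), pacSC (day 21), rST (day 35) and elST (day 56), with 3 libraries of each. The labels do not spell these names out; in the field, SG, SC and ST usually stand for spermatogonia, spermatocytes and spermatids. The series text speaks of duplicates, while the labels give 3 numbered samples per type, and all 3 were used. No label says whether the 3 came from separate animals or preparations, so p-values measure only the spread between these libraries, which may be technical.

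The authors deposited 1 table of FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for 13218 loci, with 1 column per library. Per the submitters' processing notes, HISAT2, StringTie and the mm10 build were used, with no versions given. The annotation, the counting of strand, the filters and the denominator of the FPKM are not given in the sources used here. The gene identifiers and positions were compared with the GENCODE M21 annotation of the same assembly: 13191 loci matched by identifier, 27 did not, and 13098 had the same start and end. By M21 type, 13103 loci were long noncoding and 88 were of other types. A further 14 identifiers stood on more than 1 row, with 21 extra rows, and each row was kept. Another 994 rows were at 0 in every library. Coordinates are 1-based on mm10.

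Depth was inferred from the FPKM steps, since the table holds no read totals. In 2299 genes with a single exon, low values were whole multiples of a step that gives the number of fragments behind the scale. Within a tolerance of 0.02, 97.5 to 99.6% of the low values came out whole in each library. The inferred depth was 31.5 to 92.4 M (mega) fragments and the inferred fragment length 190 to 260 bp. On simulated data the estimator recovered depth within 0.43% and fragment length within 10 bp. Depth and fragment length split the libraries into 2 sets, called batch I and batch II here, which also differ in the level of a ribosomal RNA-derived locus (AY036118, divided at 100 FPKM). Batch I held the 3 priSG-B libraries, pacSC replicates 1 and 2 and elST replicate 3. The other 12 libraries formed batch II. The labels name no batch. The kit named in the labels does not mark strand, so reads of an antisense gene and of the gene it overlaps could not be told apart where their exons overlap.

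Values were tested as log2(FPKM + 1), with loci kept at 1 FPKM or more in at least 3 libraries (4117 loci). Fold changes are on this scale, which understates the change of low genes. Counts tests were not applied, because the values are FPKM. The main test was limma 3.58.1 in R 4.3.3 with a mean-variance trend and robust estimation, fitted to all 18 libraries with 1 coefficient per type, two-sided. Each type was compared with the one before it by age, with Benjamini-Hochberg adjustment over the loci of each comparison and a threshold of 0.05. An F test from the same fit asked for differences among the 6 types. Stage-enriched genes passed the threshold with a log2 fold change of at least 1 against each other type. Gene sets were tested with camera (preset correlation 0.01), adjusted over 10 tests, with an estimated correlation and fry as alternatives. On simulated values with the residual spread of these data, the test of priSG-B against priSG-A recovered 12% of the genes changed by 1 on the log2 scale, 36% at 2, 82% at 4 and 98% at 6, over 4117 genes and with 2 false calls. The other comparisons gave 5 to 8 false calls. Each gene was drawn independently, without shifts shared by a whole library, so these numbers do not give the false calls of the real data. Tables were made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9.

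The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. Because the table holds long noncoding loci, the rule took up to 6 risen and 6 fallen genes per comparison, whatever their symbol, among called genes whose 3 libraries of one type did not overlap those of the other and whose mean reached 1 FPKM in the higher type. It also took up to 4 called members of each list, 2 long noncoding genes each way and 3 stage-enriched genes per type under the same conditions. The rule did not take H19, Malat1, Snhg1, Gas5, Pvt1, Meg3, Terc, Gm47551, Gm37750, AY036118 or the RIKEN-named genes, which were chosen after their values were seen. The same holds for Gm44145 and Gm38948. Some genes that the rule took are not reported here. Of the 23 lists, 22 had no member in the table (germ cell stage genes, piRNA pathway, metabolic isoforms, cell cycle, DNA methylation, X-linked housekeeping genes and their retrocopies, mitochondrial and ribosomal protein genes, and markers of Sertoli, Leydig, myoid, fibroblast, endothelial, macrophage and erythroid cells). Cell purity was therefore not analysed here with marker genes. The list of known long noncoding RNAs had 28 members in the table, and 24 were tested.

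The alternatives were quantile normalization, no filter, a filter of 5 FPKM in 3 libraries, a pseudocount of 0.1, limma without trend and robust estimation, the replicate number as a block, the 6 libraries of a comparison alone, a log2 fold change of at least 1, and leaving out libraries. Chosen after seeing the data were the batch as a term, batch II alone, the fit without loci under 300 bp, and the fit without the 5 libraries whose mean correlation with their type was the lowest of it and under 0.8. Quantile normalization moved the median log2 fold change over all genes from -0.21 to -0.04 for priSG-B against priSG-A, from 0.42 to 0.13 for plpSC against priSG-B, from 0.58 to 0.03 for pacSC against plpSC, from -0.35 to 0.09 for rST against pacSC and from 0.17 to 0.04 for elST against rST.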

Results

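Long noncoding transcripts were profiled by RNA sequencing in 6 germ cell types of the mouse testis, from postnatal day 6 to day 56, with 3 libraries per type. The table covers 13218 loci in FPKM, of which 4117 reached 1 FPKM in at least 3 libraries and were tested. The inferred depth ranged from 31.5 to 92.4 M fragments (mega, from the FPKM steps) per library, and between 1342 and 2866 loci reached 1 FPKM in a library.

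The libraries were compared with each other first, since every comparison rests on the spread within a type. The 3 priSG-B libraries were alike, with Pearson's r of 0.97 to 0.98 across genes on the log2 scale (genes are not independent replicates). In the other types the replicates differed. Of the 18 pairs within a type, 11 had r below 0.8, and the lowest was 0.03, between rST replicates 1 and 3. Of the 135 pairs between types, 19 reached 0.9, among them pacSC replicate 2 with elST replicate 3 (0.98) and priSG-A replicate 2 with plpSC replicate 2 (0.97). The closest library carried another type label for 13 of the 18 libraries. The 5 libraries with a partner of their own type compare with a mean of 2.11 under permuted labels (permutation test, one-sided, 100000 permutations, p = 0.11). The lowest chi-square per degree of freedom against counting error alone was 1.58, between pacSC replicate 1 and elST replicate 3, which carry different labels, and the lowest within priSG-B was 1.77. All 18 libraries were kept, and these values do not show whether libraries came from separate samples.

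**Figure D1:**
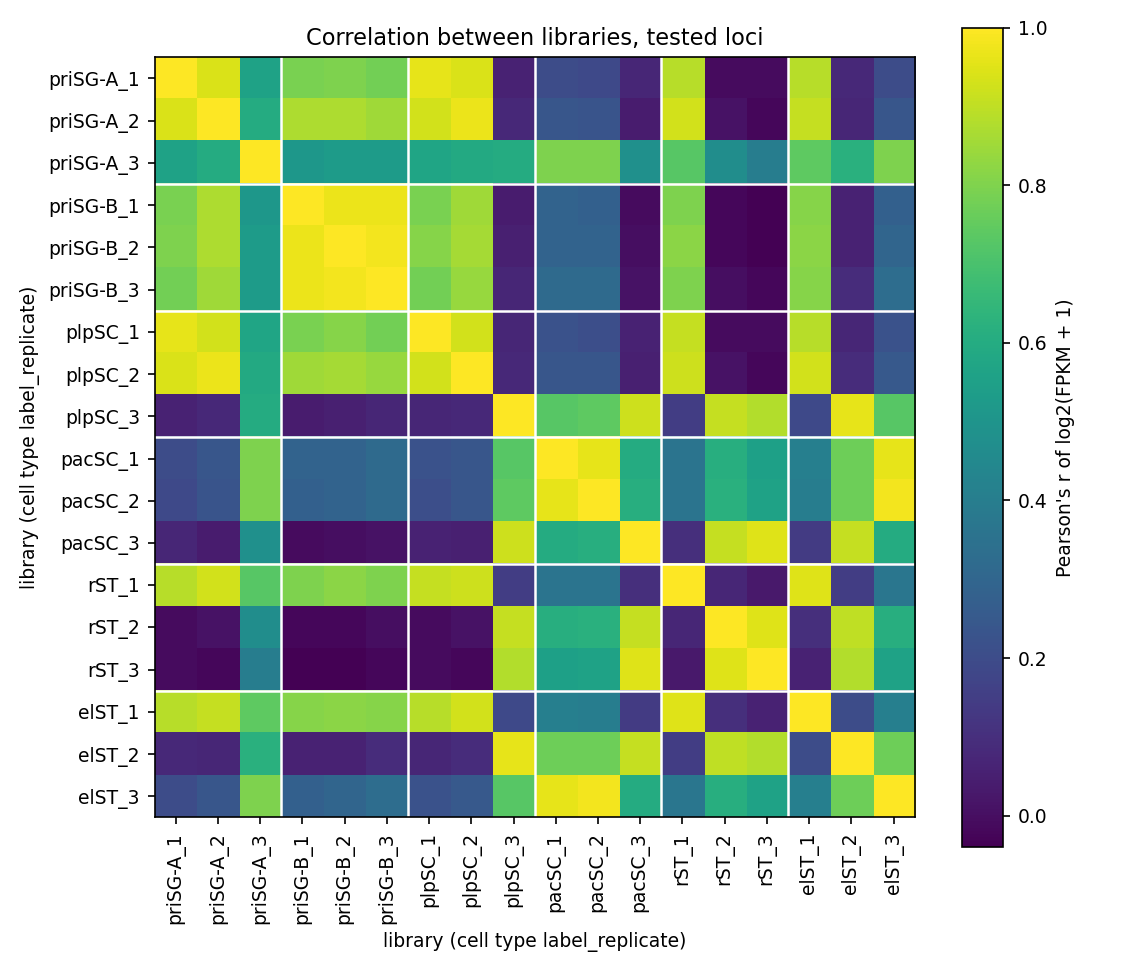
Pearson's r of log2(FPKM + 1) over the 4117 tested loci for each pair of the 18 libraries, with white lines between the type labels. The priSG-B block lies at 0.97 to 0.98, while rST replicate 1 has r of 0.03 with rST replicate 3 and 0.95 with elST replicate 1.

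The imprinted transcript H19 and the nuclear transcript Malat1 show this spread gene by gene, and were chosen after their values were seen, as were Snhg1, Gas5 and Pvt1. H19 (chromosome 7, 142575529 to 142578143) stood at 234, 82.4 and 1.45 FPKM in the 3 priSG-A libraries and at 33.7, 32.7 and 34.8 FPKM in priSG-B. In plpSC it stood at 15.3, 29.6 and 0.562 FPKM, in rST at 6.44, 0.286 and 0.810 FPKM, and in elST at 12.4, 0.553 and 0.436 FPKM. The pacSC libraries held 0.450, 0.560 and 0.677 FPKM. Malat1 (chromosome 19, 5795690 to 5802672) stood at 2854, 1393 and 616 FPKM in priSG-A and at 3183, 1361 and 149 FPKM in plpSC.

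The first comparison asked which long noncoding genes differ between the day 6 type, priSG-A, and the day 9 type, priSG-B. In priSG-B, 27 genes had risen and 1 was lower by limma at an adjusted p under 0.05. By M21 type they were 10 antisense genes, 9 lincRNAs, 6 genes marked TEC (a class of loci still awaiting experimental proof), 2 processed transcripts and 1 sense intronic gene. On the log2(FPKM + 1) scale, which understates the change of low genes, the largest rise was that of the lincRNA Gm48610 (chromosome 12, 4572401 to 4576756). It went from 6.07 ± 4.36 to 160 ± 16.0 FPKM (SD, n = 3 each), a log2 fold change of 4.67 ± 0.96 (SE, limma adjusted p = 0.0347). Gm37214 (chromosome 1, 183420655 to 183422213), inside Hhipl2 on the same strand without sharing an exon, rose from 1.15 ± 0.754 to 23.04 ± 2.09 FPKM, a log2 fold change of 3.53 ± 0.58 (limma adjusted p = 0.00611). Reads of Gm37214 could not be separated from those of unspliced Hhipl2 RNA. Appbp2os (chromosome 11, 85234775 to 85238304), which overlaps exons of Appbp2 on the other strand, rose by 3.24 ± 0.59. Its reads could not be separated from those of Appbp2.

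Ftx (chromosome X, 103560907 to 103623790), a noncoding gene of the X-inactivation centre, rose from 4.31 ± 2.04 to 38.1 ± 4.39 FPKM (log2 fold change 2.96 ± 0.61, limma adjusted p = 0.0347). It was 1 of 2 called members of the list of known long noncoding RNAs, both over all genes tested and adjusted over the list alone. The other was Rmrp (chromosome 4, 43492783 to 43493063), the RNA component of RNase MRP, which is listed at 0 in all 3 priSG-B libraries and at 5423, 54480 and 15181 FPKM in priSG-A. It is 281 bp long and shares exon sequence with Ccdc107 on the other strand, and an exact 0 of so short a locus cannot be told from a failed estimate. The small nucleolar RNA host gene Snhg1 stood at 37.5, 54.1 and 19.09 FPKM in priSG-A and at 90.03, 91.2 and 106 FPKM in priSG-B, which did not pass the test (limma adjusted p = 1). As a set, the 24 list members were not called (camera adjusted p = 0.0622; with an estimated correlation, adjusted p = 0.693), with a median log2 fold change of 0.57 and a mean of -0.14.

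**Figure D2:**
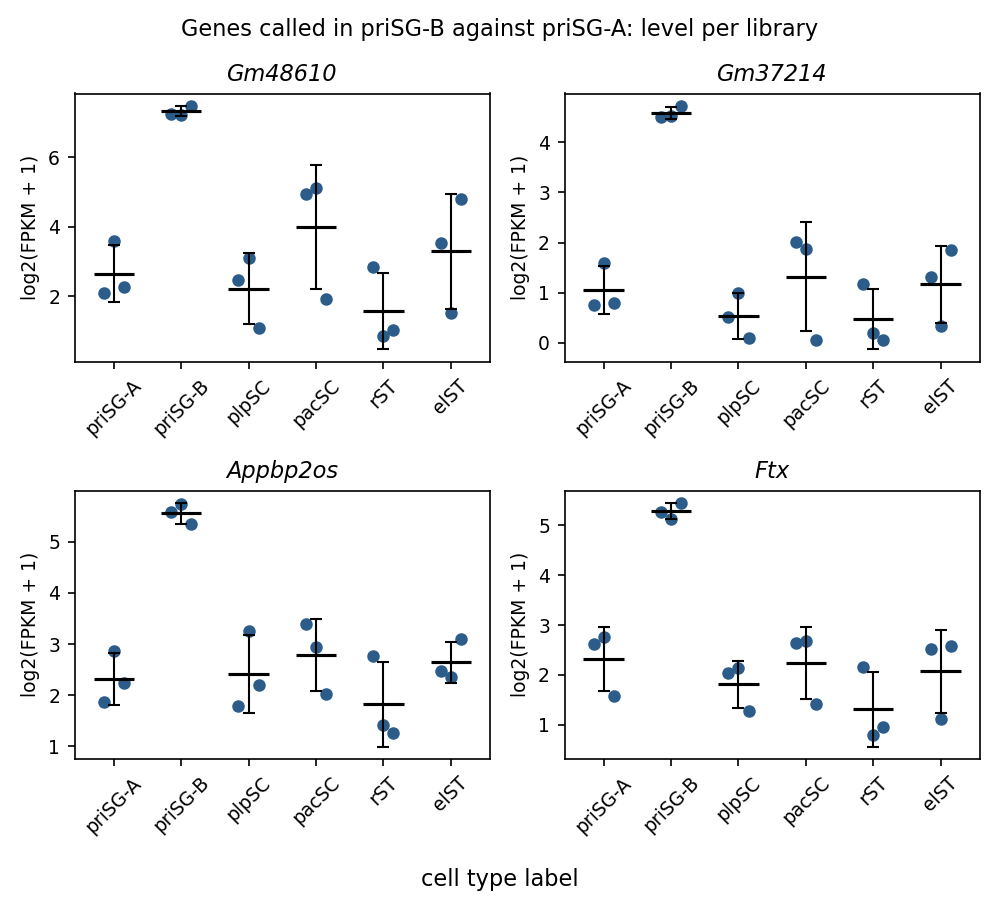
Level of Gm48610, Gm37214, Appbp2os and Ftx, 4 genes called in priSG-B against priSG-A, as log2(FPKM + 1) on the y axis and type label on the x axis. Points are libraries, horizontal bars the means and error bars the SD (n = 3). All 3 priSG-B libraries lie above every other library in each panel.

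All 3 priSG-B libraries belong to batch I and all 3 priSG-A libraries to batch II, so no value within 1 batch can be had for this comparison. Over the 27 risen genes, the other batch I libraries (pacSC replicates 1 and 2 and elST replicate 3) stood at a median of 13.3% of the priSG-B level, with a range of 1.6 to 24.8%. With batch as a term, which pacSC and elST alone can estimate, 140 genes were called (14 higher, 126 lower), and 13 of them were among the 28. That estimate rests in part on pacSC replicate 3 and elST replicate 1, which stood apart from their types. It may therefore carry their differences as well as those of batch. A pseudocount of 0.1 left 1 gene. The 6 libraries alone gave 505 (273 higher, 232 lower). A fit without the 5 libraries that stood apart from their type (priSG-A, plpSC and pacSC replicate 3, rST and elST replicate 1), a choice made from the profiles themselves, gave 424 (170 higher, 254 lower). Leaving out priSG-A replicate 1 or 3 gave 16 and 14 genes, and leaving out priSG-B replicate 1, 2 or 3 gave 8, 7 and 6.

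The calls of Gm48610, Gm37214, Appbp2os and Ftx were each lost with a pseudocount of 0.1, without replicate 1, 2 or 3 of every type, and with batch as a term, which gave log2 fold changes of 1.98, 2.08, 2.33 and 1.95. Those of Gm48610, Appbp2os and Ftx were also lost after quantile normalization. The log2 fold changes of these 3 were then 4.40, 3.34 and 2.98, and 4.91, 3.51 and 3.25 with the pseudocount of 0.1. Over the alternatives the limma adjusted p ranged from 0.00673 to 1 for Gm48610 and from 0.00214 to 1 for Ftx, and the sign did not change. Of all 27 risen genes, 12 kept their call with batch as a term. Rmrp lost its call only without replicate 1, 2 or 3 of every type.

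The second comparison set the day 14 type, plpSC, against priSG-B. In plpSC, 51 genes had fallen and 1, Rmrp, was higher, while the median log2 fold change over all genes was 0.42. Gm48610 fell to 4.41 ± 3.22 FPKM (log2 fold change -5.10 ± 0.96, limma adjusted p = 0.0145). Gm12953 (chromosome 4, 116551740 to 116552627), which overlaps exons of Tmem69 on the other strand, fell from 44.5 ± 5.81 to 1.96 ± 1.35 FPKM, a log2 fold change of -4.07 ± 0.85. The reads of Gm12953 could not be separated from those of Tmem69. Gm37214 fell to 0.497 ± 0.472 FPKM (-4.05 ± 0.58, limma adjusted p = 0.00129). The lincRNA Gm45184 (chromosome 7, 127434422 to 127439392) fell from 46.4 ± 5.52 to 2.27 ± 1.59 FPKM, and Gm43461 (chromosome 5, 147427738 to 147428733), marked TEC, from 39.7 ± 4.10 to 1.99 ± 1.40 FPKM. Gm42687 (chromosome 3, 115910370 to 115910533), a locus of 164 bp that overlaps Dph5 on the same strand, is listed at 39.3, 94.8 and 136 FPKM in priSG-B and at 0 in all 3 plpSC libraries. It is also listed at 168 FPKM in elST replicate 3, a batch I library, and at 0 in elST replicates 1 and 2. As for Rmrp, an exact 0 of so short a locus cannot be told from a failed estimate. Reads of Gm42687, which shares no exon with Dph5, could not be separated from those of unspliced Dph5 RNA.

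Of the known long noncoding RNAs, Ftx fell to 2.64 ± 1.06 FPKM in plpSC (-3.47 ± 0.61, limma adjusted p = 0.00799). Rmrp is listed at 5695, 65601 and 2188 FPKM there. These 2 were again the called members, also when adjusted over the list alone. Snhg1 stood at 26.5, 45.5 and 2.04 FPKM and Gas5, another small nucleolar RNA host gene, at 92.5, 133 and 37.1 FPKM, against 166, 166 and 177 FPKM in priSG-B, and neither passed (limma adjusted p = 0.522 and 0.671). As a set the list was called lower in plpSC only with the preset correlation of 0.01, with a median log2 fold change of -0.85 and a mean of -0.29 (camera adjusted p = 0.000283). The correlation estimated from the data was 0.284, and with it the set was not called (camera adjusted p = 0.693), nor with fry (adjusted p = 0.728). With batch as a term the median was -0.23 (camera adjusted p = 0.0413). The set call was lost without replicate 3 of every type (camera adjusted p = 0.266).

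The plpSC libraries all belong to batch II, so no value within 1 batch can be had here either. Ftx stood at 5.26 and 5.43 FPKM in pacSC replicates 1 and 2 and at 5.01 FPKM in elST replicate 3, the other batch I libraries. With batch as a term, 61 genes were called, 46 higher and 15 lower, against 1 higher and 51 lower without it. A pseudocount of 0.1 left 2 genes. The 6 libraries alone gave 155 (35 higher, 120 lower), and the fit without the 5 libraries that stood apart gave 461 (271 higher, 190 lower). Leaving out priSG-B replicate 1, 2 or 3 gave 11, 10 and 9 genes, and leaving out plpSC replicate 1 or 3 gave 21 and 23. The calls of Gm48610, Gm12953, Gm37214, Gm45184, Gm43461 and Ftx were each lost with a pseudocount of 0.1, with batch as a term, and without replicate 1, 2 or 3 of every type. After quantile normalization Gm12953 and Gm37214 kept theirs and the other 4 did not, with log2 fold changes of -4.99 for Gm48610, -4.23 for Gm45184, -4.09 for Gm43461 and -3.75 for Ftx. With batch as a term those of the 4 were -2.41, -2.15, -2.20 and -2.46.

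All 27 genes that had risen in priSG-B against priSG-A were among the 51 that fell in plpSC. Both comparisons use the same priSG-B libraries. With no effect, the overlap of lists of these sizes averaged 6 and reached at most 11 in 100 simulations, and independent lists would share 0.33. The simulated comparisons share priSG-B libraries too, so random spread shared in this way is already in that average. Any difference of the 3 priSG-B libraries from the others, by type, batch or preparation, would give such an overlap. It is therefore no separate evidence for a peak at day 9, and the 3 libraries are too few to split. The F test over the 6 types called 28 genes, of which 24 were also called in priSG-B against priSG-A. Stage-enriched genes numbered 24 in priSG-B and 0 in each other type. Gm37214 was among the 3 with the largest smallest fold change. Without replicate 1 or 2 of every type the F test called 0 genes and priSG-B enrichment 0. Without replicate 3 they called 178 and 1, and 76 genes were then enriched in pacSC. Without the 5 libraries that stood apart, 48 were enriched in priSG-B and 491 in rST. Every called gene of both comparisons was long noncoding by M21, against 98.6% of the genes not called (Fisher's exact test across genes, p = 1 for each).

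The third comparison set the day 21 type, pacSC, against plpSC. H19 stood below 1 FPKM in all 3 pacSC libraries and at 15.3, 29.6 and 0.562 FPKM in plpSC (limma adjusted p = 0.311). Pvt1, a noncoding gene beside Myc, stood at 6.36, 7.22 and 5.72 FPKM in pacSC and at 0.490, 0.443 and 8.41 FPKM in plpSC (limma adjusted p = 0.360). The gene with the smallest p, named after its values were seen, was the lincRNA 1700014F14Rik (chromosome 5, 60940938 to 60945649), at 16.5, 20.4 and 1.85 FPKM in pacSC and listed at 0 in all plpSC libraries. No gene passed in limma (smallest adjusted p = 0.226), and 650 had an unadjusted p under 0.05, where 206 are expected by chance. That number was 141 and 146 without plpSC replicate 1 or 2, 152 and 127 without pacSC replicate 1 or 2, 2253 without plpSC replicate 3 and 65 with batch as a term. Limma without trend and robust estimation also called 0. As a set the known long noncoding RNAs were called lower in pacSC with the preset correlation, with a median log2 fold change of -0.16 (camera adjusted p = 0.00797). With an estimated correlation they were not called (camera adjusted p = 0.693), nor with fry (adjusted p = 0.728). After quantile normalization the median was -1.32 (camera adjusted p = 0.0074), and with batch as a term it was -0.47. Without plpSC replicate 3, which had r of 0.07 and 0.08 with the other plpSC libraries, 1197 genes passed (898 higher, 299 lower), and without pacSC replicate 3, 3 passed.

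**Figure D3:**
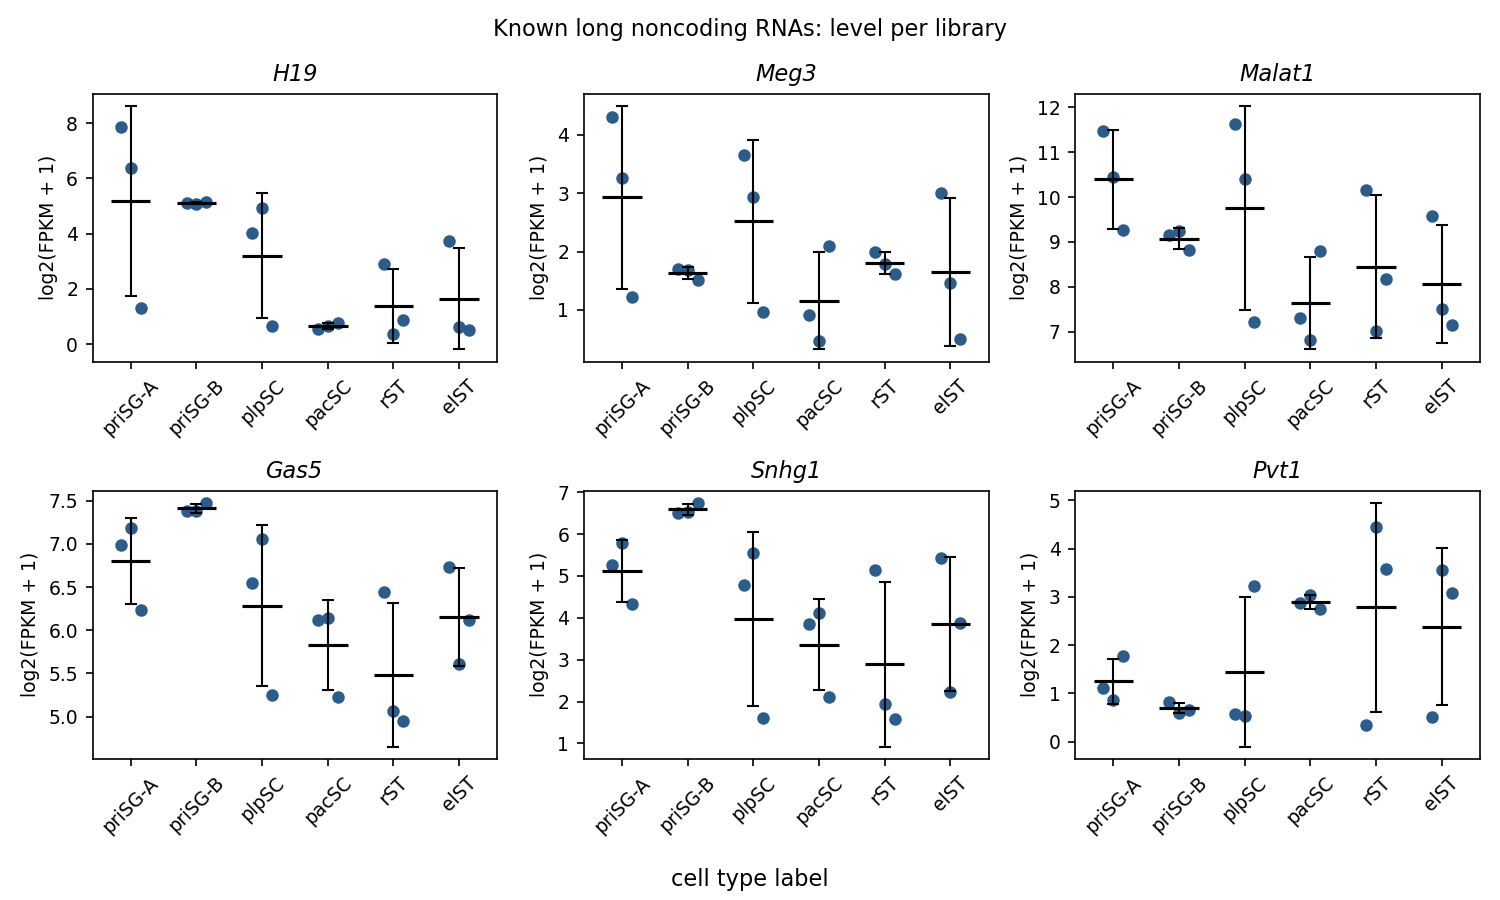
Level of 6 known long noncoding RNAs, as log2(FPKM + 1) on the y axis and type label on the x axis. Points are libraries, horizontal bars the means and error bars the SD (n = 3). H19 spans 1.45 to 234 FPKM within priSG-A but 32.7 to 34.8 FPKM within priSG-B.

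The fourth comparison set the day 35 type, rST, against pacSC. Pvt1 stood at 0.264, 20.8 and 10.9 FPKM in rST, and Snhg1 at 34.5, 2.83 and 1.99 FPKM in rST against 13.5, 16.3 and 3.33 FPKM in pacSC. Gm44145 (chromosome 6, 82680132 to 82694822), an antisense gene that overlaps Pole4 and was named after its values were seen, stood at 96.4, 59.0 and 6.69 FPKM in pacSC and is listed at 0 in all 3 rST libraries (limma adjusted p = 0.498). No gene passed in limma, 372 had an unadjusted p under 0.05, and limma without trend and robust estimation called 0. That number was 59, 68 and 828 without pacSC replicate 1, 2 or 3, 636, 219 and 206 without rST replicate 1, 2 or 3, and 34 with batch as a term. Without pacSC replicate 3, 1 gene passed. The known long noncoding RNAs were not called as a set (camera adjusted p = 0.575), with a median log2 fold change of -0.24 where camera gave the direction up, and the median was 0.34 after quantile normalization.

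The last comparison set the day 56 type, elST, against rST. The lincRNA Gm38948 (chromosome 7, 15971883 to 15984654), which shares exon sequence with Bicra on the other strand and was named after its values were seen, had the smallest p, at 1.04, 3.39 and 1.62 FPKM in rST and 0.265, 0.497 and 0.0725 FPKM in elST (limma adjusted p = 0.882). Malat1 stood at 1140, 129 and 287 FPKM in rST and at 763, 179 and 140 FPKM in elST. No gene passed in limma, 78 had an unadjusted p under 0.05, and limma without trend and robust estimation called 0. The number at an unadjusted p under 0.05 was 797, 19 and 17 without rST replicate 1, 2 or 3, and 300, 199 and 12 without elST replicate 1, 2 or 3. The known long noncoding RNAs were not called as a set (camera adjusted p = 0.149), with a median log2 fold change of 0.49. Without elST replicate 1, 1 gene passed. Within batch II, with 3 rST and 2 elST libraries, 0 genes passed and 8 had an unadjusted p under 0.05. Batch II holds 1 pacSC library, assumed to vary like the other groups, and the 0 genes called within it against plpSC or rST say nothing about stability. Without the 5 libraries that stood apart, the last 3 comparisons called 2793, 2282 and 1621 genes.

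Genes on chromosome X, whose silencing in pachytene spermatocytes is textbook knowledge, were tested as a set of 78 over the 5 comparisons, and none of the tests passed at the settings used for the counts above. With the filter of 5 FPKM, camera placed the set below other genes in pacSC against plpSC and above them in rST against pacSC. With batch as a term it placed the set above other genes in priSG-B against priSG-A and below them in plpSC against priSG-B. For pacSC against plpSC, camera placed the set below other genes (adjusted p = 0.0622; with an estimated correlation, adjusted p = 0.693), although its median log2 fold change was 0.43, against 0.58 for all genes. After quantile normalization the median of the set was -0.04 there and 0.06 for rST against pacSC, where it was -0.40 without it. The X-linked gene 4930570D08Rik (chromosome X, 133898699 to 133901213), named after its values were seen, is listed at 0 in plpSC replicates 1 and 2 and stood at 599.9 FPKM in replicate 3. It stood at 575, 602 and 1311 FPKM in pacSC. The share of X-linked loci at 1 FPKM or more, also computed after seeing the data, was 52.6%, 46.2% and 67.9% in pacSC, against 65.1%, 65.5% and 64.8% of autosomal loci. In elST it was 39.7%, 66.7% and 42.3% against 40.4%, 66.8% and 64.4%, and in rST 32.1%, 50% and 61.5% against 37.2%, 58.5% and 57.9%. In plpSC it was 37.2%, 32.1% and 65.4% against 35.1%, 36.6% and 65.3%. Camera's direction and the sign of the set's median also differed for priSG-B against priSG-A, plpSC against priSG-B, rST against pacSC and elST against rST (camera adjusted p = 0.265, 0.395, 0.149 and 0.408).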

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

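Batch as a term, the fit without the 5 libraries that stood apart, the fit without loci under 300 bp and batch II alone were chosen after seeing the data; the other alternatives were planned. In what follows the comparisons are B/A (priSG-B against priSG-A), plp/B, pac/plp, rST/pac and elST/rST, and the cause of a change was not tested unless given. No called set turned camera's direction. For single genes, signs were compared for the named ones only, and these kept their side of the threshold in 45 cases and lost it in 75, with the same sign. The split of higher and lower calls did turn, in B/A from 27 and 1 to 14 and 126 with batch as a term and 170 and 254 without the 5 libraries, and in plp/B from 1 and 51 to 46 and 15 and to 271 and 190.

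Without a filter the counts went from 28, 52, 0, 0 and 0 to 76, 118, 3, 3 and 1, the F test from 28 to 90, and the known list in pac/plp missed the threshold (median -0.08). With 5 FPKM in 3 libraries B/A gave 10, plp/B 21, the F test 9 and priSG-B enrichment 8 in place of 24, over fewer genes, and sets passed for the known list in B/A (0.77) and elST/rST (0.67) and for X in pac/plp (median 1.23, camera down) and rST/pac (-0.17, camera up). With a pseudocount of 0.1 B/A gave 1, plp/B 2, the F test 1 and priSG-B enrichment 0, and the known list passed in B/A (0.63). Quantile normalization turned the sign of 3 set medians, none of them called (X in pac/plp to -0.04 and in rST/pac to 0.06, and the known list in rST/pac to 0.34), moved the called medians of the known list to -1.25 in plp/B and -1.32 in pac/plp, gave 43 in the F test, and of its 28 calls in B/A 21 were shared with the main ones. The 6 libraries alone gave 505 in B/A and 155 in plp/B.

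With batch as a term B/A gave 140, the F test 148 and priSG-B enrichment 10, and X passed in B/A (median 0.24, where it was -0.34, camera up) and plp/B (0.10, camera down). The known list then had medians of 0.09 in B/A, -0.23 in plp/B and -0.47 in pac/plp. Without the 5 libraries the counts were 424, 461, 2793, 2282 and 1621, the F test 3630, and enrichment 48 in priSG-B, 1 in pacSC and 491 in rST. The known list then missed in plp/B (-0.58) and X passed in pac/plp (0.54, camera down). These 5 were picked by their profiles, which by itself lowers the spread. Of them, pacSC replicate 3 and elST replicate 1 also enter the estimate of the batch term, which may carry their differences. Without loci under 300 bp, Rmrp among them, the known list passed in B/A (0.61). With an estimated correlation or fry the known list missed in plp/B (-0.85) and pac/plp (-0.16).

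Leaving out 1 library gave 6 to 23 in B/A (16 and 14 without priSG-A replicates 1 and 3, and 8, 7 and 6 without priSG-B replicates 1, 2 and 3) and 9 to 62 in plp/B (11, 10 and 9 without priSG-B replicates 1, 2 and 3, and 21 and 23 without plpSC replicates 1 and 3). It gave 0 to 1197 in pac/plp, 0 to 1 in rST/pac and 0 to 1 in elST/rST. Leaving out a replicate number from all types gave 0 to 178 in the F test, 0 to 1 for priSG-B enrichment and 0 to 76 for pacSC. Medians of the known list were then 0.32 to 0.85 in B/A, -1.09 to -0.56 in plp/B, -0.36 to -0.07 in pac/plp, -0.59 to -0.08 in rST/pac and 0.34 to 0.68 in elST/rST. Those of X were 0 to 0.96 in plp/B, 0.24 to 0.50 in pac/plp, -0.64 to 0.07 in rST/pac and -0.19 to 0.32 in elST/rST, so the last 2 changed sign, as did X in B/A without replicate 3 (0.01). The known list then passed in B/A without replicate 1 or 2, and in rST/pac and elST/rST without replicate 2. It missed in plp/B without replicate 3. X passed in pac/plp without replicate 1 or 3, in rST/pac without 3 and in elST/rST without 2, with camera's directions unchanged, so these sets are called or not by single replicate numbers.

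The replicate numbers were not taken to pair the libraries, since not every same-numbered pair deviated together: 25 of 45 same-numbered pairs had deviations correlated above 0.1, the lowest r was -0.83, and 11 of 18 libraries were closest to their own number. The median r was 0.13 for the same number and -0.10 for different numbers, so some link is left open. The fit with the replicate number as a block gave 31 in B/A, 59 in plp/B and 0 in the others, with 1157 genes at an unadjusted p under 0.05 in pac/plp against 650 without the block. The limit set by depth was not tested apart from that of the spread. The shallowest library held 31.5 M fragments, and with the spread of these data 12% of simulated changes of 1 on the log2 scale were found in B/A.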

Other observations

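The tests in this part were all chosen after the results they bear on had been seen, the counts over other splits included, and so were the genes named here.

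Many tested loci carry RIKEN clone names, and the name shows the library a clone came from. Of 863 tested loci named after clones of adult testis libraries, plpSC replicate 3 held 89.9% at 1 FPKM or more, against 9.8% and 10.7% in plpSC replicates 1 and 2. The share was 10.7%, 10.2% and 57.6% in priSG-A, 10.2%, 10.1% and 10.9% in priSG-B and 81.2%, 81.8% and 89.1% in pacSC. It was 14.4%, 86.1% and 85.4% in rST and 18%, 90.4% and 80.8% in elST. The 363 loci named after other RIKEN clones varied less, from 34.2% in rST replicate 3 to 61.4% in priSG-A replicate 3. The first principal component, with 74.8% of the variance, ran from -66.6 in priSG-A replicate 2 to 85.2 in pacSC replicate 3, with priSG-A replicate 3 at 2.5.

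Among the genes at its ends, 1700027A15Rik (chromosome 1, 72984844 to 73025507) overlaps exons of the transition protein gene Tnp1 on the other strand, and Tnp1 is a spermatid gene. Without strand its reads cannot be separated from those of Tnp1. It stood at 4539 and 3175 FPKM in rST replicates 2 and 3 and at 0 in rST replicate 1, at 874 FPKM in plpSC replicate 3 and 0 in the other plpSC libraries. In pacSC it stood at 75.8, 84.9 and 1195 FPKM and in elST at 0.570, 875 and 73.0 FPKM. At the other end, the telomerase RNA Terc stood at 491, 392 and 524 FPKM in priSG-B, at 12.8, 77.5 and 17.2 FPKM in priSG-A and at 52.4, 1.32 and 0 FPKM in rST. Gm47551 (chromosome 13, 98801172 to 98803736), overlapping Fcho2 on the other strand, stood at 11595, 7654 and 11390 FPKM in priSG-B, at 1353 and 2151 FPKM in pacSC replicates 1 and 2 and at 25.5 FPKM in pacSC replicate 3.

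Libraries of one label differed more than some libraries of different labels. The division into batch I and II is argued against as the cause in rST, plpSC and priSG-A, which lie in batch II alone. Their lowest r was 0.03, 0.07 and 0.56. In elST the batch II replicates 1 and 2 had r of 0.20. In pacSC the difference followed the batch: replicates 1 and 2 (batch I) had r of 0.96, and 0.60 and 0.61 with replicate 3 (batch II). Batch therefore stays open for pacSC, and a batch other than these sets was not tested. Wrong labels on some libraries or columns remain a candidate explanation, since 2 pairs of different types reached the lowest r within priSG-B (0.97). These were pacSC replicate 2 with elST replicate 3, in batch I, and priSG-A replicate 2 with plpSC replicate 2, in batch II. Each pair thus shares a batch, and a part of batch in their high r was not separated from the labels. By chi-square per degree of freedom, elST replicate 3 was closer to pacSC replicates 1 (1.58) and 2 (2.09) than these were to each other (3.18). The rST label lies between pacSC and elST by age, yet the rST libraries had r of 0.36 to 0.62 with pacSC replicates 1 and 2. With pacSC replicate 3, which like rST is in batch II, rST replicates 1, 2 and 3 had r of 0.10, 0.91 and 0.95. The lower values with pacSC replicates 1 and 2 therefore cannot be told apart from batch. Similar types could give a high r too, which was not tested. A mixture holding at least 10% of a library's own type was tested on genes abundant in the other libraries of the type and low in the closest library of another type. Their median level was 2.8% in plpSC replicate 3 and 0.1% in rST replicate 1, below 10%. The closest library was picked by its likeness to the library tested, which favours low levels of these genes. The test therefore does not by itself exclude a mixture there. In pacSC replicate 3 (6.9%) the quartiles (3.7 to 11%) span 10%, and in elST replicate 1 (1.8%) the other elST libraries differ too much (r = 0.77) to decide. In priSG-A replicate 3 the level was 38.4%, so a mixture may account for it, but its genes include the ribosomal RNA-derived AY036118, which differs by batch, and H19 stood at 1.45 FPKM against 234 and 82.4; differences of biology between preparations were not tested.

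Batch was weighed for the genes that differed in priSG-B. For the 27 risen genes called in all 18 libraries, the other batch I libraries exceeded batch II by a median log2 ratio of 0.31 (quartiles 0.07 to 0.61), against 2.02 for priSG-B over priSG-A. They stood at 1.6 to 24.8% of the priSG-B level. Batch I alone thus did not bring pacSC or elST to the priSG-B level. The 2 sides of the ratio hold different types, so it does not separate batch from type. Within pacSC, Gm48610, Gm37214, Appbp2os and Ftx were each higher in batch I. Gm48610 stood at 29.9 and 33.5 against 2.80 FPKM and Ftx at 5.26 and 5.43 against 1.66 FPKM. The batch II side there, pacSC replicate 3, stood apart from its type. A batch shift as the whole cause is therefore not excluded for these 27. With batch as a term their median log2 fold change went from 2.03 ± 0.31 to 1.61 ± 0.42 (median SE) and 12 were still called, so a part due to batch may remain, and the median fold was smaller and the median SE larger. The fit of 18 libraries favours genes that vary little between the libraries within each type, so the test was repeated on genes called in the 6 libraries alone. There the ratio was 0.16 (quartiles -0.20 to 0.77) against 1.03 over 273 risen genes, and -0.30 (quartiles -0.84 to 0.11) against -0.97 over 232 fallen genes. The quartiles reach past the halfway point, so batch and type cannot be told apart for these wider sets either. The age of the animals, and an effect of the preparation of the priSG-B libraries alone, stay open and were not tested.

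Extreme FPKM and exact zeros in single libraries may come from short loci. Among loci that reach 100 FPKM, 38.2% of the values were exactly 0 in the 25 loci under 300 bp and 14.7% in the 169 longer ones. Short loci were 1% of the loci and 2.4 to 88.4% of a library's FPKM sum. Gm37750 (129 bp) was listed at 132253 FPKM in rST replicate 1 and at 0 in rST replicate 3. It was at 0 in every batch I library, and within batch II only in rST replicate 3 and elST replicate 2. Its zeros therefore went largely with batch. No biological explanation was tested.

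Other splits of the libraries were counted, and 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real split gave 28 genes for priSG-B against priSG-A and the highest other split 1, and 52 and 0 for plpSC against priSG-B, with 1 of the 10 splits as large in each. For pacSC against plpSC the real and highest other counts were both 0. For rST against pacSC the real count was 0 and the highest other 964, from pacSC replicates 1 and 2 with rST replicate 1 against the rest. For elST against rST they were 0 and 1270, from rST replicate 1 with elST replicates 1 and 3 against the rest; in these 3 comparisons all 10 splits gave as many. In the F test 4 of 100 drawn regroupings, the real one included, gave 28 genes or more. That share is under 0.05, but with so few draws it is too close to 0.05 to exclude chance firmly, and without replicate 1 or 2 of every type the count was 0. The highest other, 1923, points to a structure of the samples that the labels do not follow.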
